A study of Rattus norvegicus with 4 samples.

How the data were processed

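RNA from the colon mucosa of F344 rats was measured on 2-colour Agilent arrays with probes 60 bases long. Per the labels, Cy5 held the resveratrol plus DSS sample of 2 rats and Cy3 the control pool on all 4 arrays, labelling was indirect, and no dye was exchanged. The control pool is treated as 1 control sample. How many of the control rats it held, and whether every array held the same pool, is not given in the sources used here. Samples were named by accession order as replicates 1 to 4 of a single group.

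The deposited scanner files hold spot intensity values from Agilent Feature Extraction 9.5.3.1 per the file headers, which also name the rn3 build for probe positions. Per the file headers, the processed intensity values had been background-subtracted, detrended and dye-normalized by the scanner software. The deposited log10 ratio of each spot equalled the ratio of the processed signals within 0.001 for 74.0% of spots and was not used for the comparison. In the value table of the authors, all 24197 probes matched the array, and its values followed the scanner's log2 ratios (Cy5 over Cy3) with r between 0.98 and 0.99 and slopes between 0.97 and 1.00, which gave scale and direction. The medians of its columns were -0.01, -0.01, 0.09 and -0.02, and how it was centred is not stated. The submitters' processing notes name Agilent Feature Extraction and limma.

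Starting from the mean spot signals and the local background medians, background was corrected with normexp at an offset of 50, and ratios were normalized within arrays by loess in limma 3.58.1 under R 4.3.3. Control spots (1639 of 45018) and outlier-flagged spots had weight 0, and spots of the same probe were averaged. A probe entered if it was well above background in at least 1 channel on at least 3 arrays, which 20409 of 41012 probes met, and 1540 of these were left with under 2 values. Of the 18869 tested, 14200 had values on 4 arrays, 1969 on 3 and 2700 on 2. The mean log2 ratio was tested against 0 with lmFit and eBayes, and p-values, all two-sided, were adjusted by Benjamini-Hochberg at 0.05. Positive values mean higher with resveratrol. Values after ± are the moderated standard errors of this fit, in which a probe's variance is drawn toward that of all probes. Where arrays differ widely they can be smaller than a standard error taken from the probe's own arrays. For probes with values on 2 arrays they lean most on the other probes.

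Gene names came from the accessions and names in the files through a RefSeq gene table of assembly GRCr8, used for names only. They were found by accession for 10735 probes, by another accession for 117, by symbol for 5537 and by synonym for 3705, the file's name was kept for 119, and 20799 stayed unnamed. A gene is represented by its brightest probe. Among 440 genes with at least 2 called probes, 61 had probes called in opposite directions.

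Before the data were examined, 38 gene lists were fixed and the genes to be named were set by rule: 6 inflammatory genes always; the 12 highest and 12 lowest genes with an official symbol, past the threshold and of the same sign on all 4 arrays; up to 4 called members of each list that passed, in its direction; and up to 2 called members of each list that did not. Some genes that the rule takes are not reported here. Lists were tested with camera at an inter-gene correlation of 0.01 (cameraPR on the moderated statistics, since some values are missing), adjusted over the 38 lists. An estimated correlation and fry, which need complete values, used genes measured on all 4 arrays. With camera and the estimated correlation 0 lists passed and 2 had an unadjusted p under 0.05, and with fry 15 passed. Antimicrobial genes and mast cell markers failed there although their estimated correlations, -0.086 and -0.04, lay below the preset 0.01. In the other lists that passed at the preset value it lay between 0.103 and 0.797. Correlation between genes is thus not the only reason for the failures, as that test also has low power with 4 arrays. Where a channel was not well above background on any array, or saturated on all, a fold is a lower bound, computed per channel after loess and Aquantile normalization.

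Tested on simulated data with a spread taken from these arrays, the fit over 18869 probes recovered 60% and 54% of 50 probes each raised or lowered by 1 on the log2 scale. It recovered 76% and 66% of those changed by 2, with 2 false calls in all. Simulated values were independent, with no error of the pool, dye effect or correlation between genes, so the false calls do not speak to such errors. For probes without values on all 4 arrays the simulated spread was too small. Alternatives were other background corrections, normalizations, filters and priors, the scanner's processed signals, the authors' table, each array left out, array weights, the slide as a random block, a wider standard error, and other list tests. Chosen after seeing the data were leaving out hexamer probes, removing base composition, probes with 4 values, and each slide alone. Hexamers were those with a z of at least 10 for presence in probes above a log2 ratio of 1.5. Other tools were version 1.17.8 of data.table, statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9.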

Results

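The series measured gene expression in the colon mucosa of F344 rats, an inbred strain, in which colitis was induced with 5% dextran sodium sulphate (DSS) in the drinking water for 5 days. DSS injures the colonic epithelium and is widely used to model ulcerative colitis. The treated rats had been fed resveratrol, a plant polyphenol, at 1 mg per kg per day for 20 days before DSS, and the control rats had received standard chow. Each of 4 two-channel arrays held RNA pooled from 2 of the 8 resveratrol rats, labelled with Cy5, against a control pool labelled with Cy3. Whether every array held the same pool is not stated. The arrays lay on 2 slides, with 2 arrays on each, and the rats behind every array were different. Between 44.1% and 49.2% of spots were well above background in Cy5 and between 42.8% and 57.1% in Cy3, and the number of arrays limits the precision.

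The comparison asked how transcript levels in DSS colitis differed with resveratrol pretreatment. As lists, neutrophil and matrix genes were lower in the resveratrol samples than in the control pool, and genes of tight junctions and of mitochondrial respiration were higher. With an estimated correlation, in a camera test of low power with 4 arrays, none of these lists passed (adjusted p = 0.608, 0.587, 0.631 and 0.705). On slide 2 alone the last pair did not pass (adjusted p = 0.0645 and 0.118). S100a8, a subunit of the neutrophil protein calprotectin, fell to a mean log2 ratio of -3.17 ± 0.23 (moderated SE, n = 4 arrays, adjusted p = 0.00388). Its partner S100a9 fell to -2.06 ± 0.27 (n = 4, adjusted p = 0.00546). The collagen gene Col3a1 fell to -2.30 ± 0.25 (n = 4; adjusted p = 0.00451) and the tight junction gene Cldn15 rose to 1.27 ± 0.12 (n = 4; adjusted p = 0.00409). Of 18869 probes tested, 4597 were higher and 4289 lower, and 784 of these had an absolute log2 ratio of at least 1, with 475 higher and 309 lower. The balance of these large changes depended on the setting: 1535 higher and 122 lower under median centring, 1353 and 163 with outlier spots kept, 591 and 166 without replicate 3, 739 and 150 on slide 1 alone, but 295 and 367 on slide 2 alone. Without probes that carry a shared hexamer they numbered 113 and 289. The hexamers were picked from the highest of these same probes, so that fall in higher probes is partly built in. Counted by gene, through each gene's brightest probe, 2428 of 9472 genes were higher and 1853 lower. Probes with a shared hexamer were brighter, by a median of 0.55 in log2 intensity over 100 random halvings of the genes. Taking the brightest probe can therefore favour them, and how far this moved the gene counts was not tested.

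Median centring of each array in place of loess gave 6852 higher and 1839 lower probes and moved the median of all probes from -0.02 to 0.20 on the log2 scale, so that higher and lower hold relative to the centring. When the standard error was multiplied by the square root of 2 to allow the control pool a spread of its own, 1456 probes were higher and 724 lower. The factor assumes that the pool varies as much as the mean of the resveratrol arrays. How many rats the pool held is not known, so this allowance may be too small or too large. Without replicate 1 the called probes numbered 3463 and without replicate 2 3410, in place of 8886. Slide 2 alone gave 1749.

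The lowest ratios included digestive enzyme, haemoglobin and antimicrobial genes. Amy2a3, a pancreatic amylase gene, was at least 23.4-fold lower (adjusted p = 0.000904, n = 4), with Cy5 not well above background on any array. Its probe is placed at positions 209434169 to 209435369 of chromosome 2 in the rn3 build. Ctrb1, which encodes the pancreatic protease precursor chymotrypsinogen, fell to -2.55 ± 0.10 (n = 4; adjusted p = 0.000915). The beta-globin genes Hbb-b1 and Hbb fell to -3.28 ± 0.14 and -2.65 ± 0.12. Mgp, which encodes matrix Gla protein, fell to -2.76 ± 0.23, and Thbs1, encoding thrombospondin, to -2.25 ± 0.14. The regenerating family genes Reg1a and Reg3a were at least 2.98-fold and 3.94-fold lower, and the chemokine gene Cxcl12 at least 3.44-fold lower, each with Cy5 not well above background on any array. The second probe of Cxcl12 gave -0.76. Such lower bounds set the control mean against the lowest signal still well above background and are open to dye bias, since no array had the dyes exchanged.

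**Figure D1:**
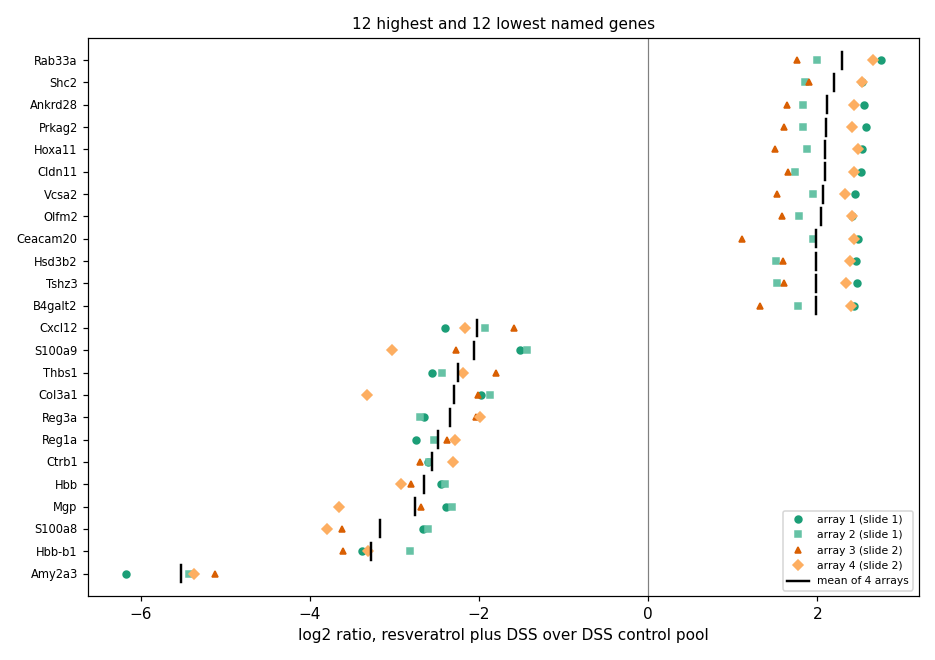
Log2 ratio of resveratrol plus DSS over the DSS control pool (horizontal axis) on each of the 4 arrays for the 12 highest and the 12 lowest named genes (vertical axis); symbols mark the arrays and black bars the means. The means of the 12 highest genes lie between 1.98 and 2.29. The points of Amy2a3, Reg1a, Reg3a and Cxcl12, whose Cy5 was not well above background, are measured ratios and not levels. Amy2a3 was at least 23.4-fold lower.

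Among the inflammatory genes chosen beforehand, Il1b, encoding interleukin-1 beta, fell to -1.33 ± 0.31 (n = 3; adjusted p = 0.0246), and its second probe gave -1.26. Without replicate 3 the Il1b value was -0.86 (adjusted p = 0.0076). With the wider standard error Il1b, Nos2 and Ptges all missed the threshold (adjusted p = 0.0962, 0.0715 and 0.0981). Nos2, the inducible nitric oxide synthase gene, was at least 1.35-fold lower (n = 4; adjusted p = 0.0147), with Cy5 not well above background, and missed the threshold without replicate 2 (adjusted p = 0.0516) and on slide 2 alone (0.0581). Ptges, encoding prostaglandin E synthase, fell to -0.66 ± 0.14 on the 2 arrays whose spots carried no outlier flag (adjusted p = 0.028), both on slide 1. Ptges missed the threshold under median centring (-0.16, adjusted p = 0.629), with processed signals (0.145) and with an intensity trend in the prior (0.0759). Ptgs2, the inducible cyclooxygenase gene, was not tested, because neither of its probes was well above background on 3 arrays. Tnf and Il6 were not well above background in either channel on any array.

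Cytokine and chemokine genes were lower as a list (camera, adjusted p = 0.007), with 8 of 15 measured members lower and 1 higher, the same numbers when adjusted over the list alone. The neutrophil attractant Cxcl2 was at least 2.98-fold and the monocyte attractant Ccl2 at least 2.23-fold lower, while Ccl3 was lower at a measured -1.36 ± 0.16, with Cy5 well above background on 1 array only. Of 10 measured anti-inflammatory mediators, 6 were lower and 1 higher (adjusted p = 0.0072; 7 and 1 adjusted over the list alone), among them Dusp1 at -0.88 ± 0.10, Il1rn at -0.76 ± 0.12, Il4 at -0.68 ± 0.14 on 3 arrays and Socs3 at -0.59 ± 0.13. Both lists had an adjusted p of 0.608 with an estimated correlation. The cytokine list also missed the threshold when both channels had to be well above background on all arrays (adjusted p = 0.622). Il4 missed it without replicate 4 (adjusted p = 0.0607), and Socs3 under median centring (-0.22, adjusted p = 0.308) and with processed signals (0.0893).

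Markers of several leukocyte types were lower. Of 9 measured neutrophil markers 7 were lower and none higher (adjusted p = 0.00271; 8 adjusted over the list alone), including Np4, on 2 arrays, and Fcgr3a at -0.55 each beside S100a8 and S100a9. Of 14 monocyte and macrophage markers 10 were lower and 1 higher (adjusted p = 0.00418; the same adjusted over the list alone), with Lyz2 at -1.06 ± 0.13 on 2 arrays, Fcgr1a at -1.02 ± 0.10, Cd163 at -0.76 ± 0.13 and Mrc1 at least 1.57-fold lower. T and NK cell markers had 7 of 13 lower (adjusted p = 0.0139; 8 adjusted over the list alone), with Cd3d at -0.75 ± 0.19, Gzmb at -0.72 ± 0.13 on 3 arrays, Cd6 at -0.60 ± 0.13 on 2 and Il7r at -0.50 ± 0.12. Mast cell and eosinophil markers had 6 of 8 lower (adjusted p = 0.0141; 7 adjusted over the list alone), with Hdc at -1.40 ± 0.38, Tpsab1 at -1.07 ± 0.34, Mcpt1 at -0.64 ± 0.14 and Mcpt4 at -0.61 ± 0.14, the last pair on 3 arrays. Without replicate 3 Hdc was at -0.87 and Tpsab1 at -0.61, and both missed the threshold without replicate 1 (adjusted p = 0.0592 and 0.066), 2 (0.0524 and 0.0591) or 4 (0.0541 and 0.0893). Mcpt1 and Mcpt4 missed it without replicate 1 (adjusted p = 0.0508 and 0.0648) or 2 (0.0725 and 0.0699). Erythrocyte and platelet markers had 8 of 9 lower and 1 higher (adjusted p = 0.00315; the same adjusted over the list alone), with Ppbp at -0.69 ± 0.15 and Alas2 at -0.66 ± 0.13, each on 2 arrays. For neutrophils, mast cells and erythrocytes the adjusted p with an estimated correlation was 0.608, and for macrophages and T cells 0.631. With both channels well above background on all arrays the macrophage and T cell lists did not pass (adjusted p = 0.0651 and 0.23). In fry T cells did not (adjusted p = 0.0784). Among single genes Cd3d and Il7r missed the threshold without replicate 2 (adjusted p = 0.0665 and 0.0507) or 4 (0.0713 and 0.0518), Gzmb without replicate 1 (0.054), Np4 without replicate 4 (0.0551) and Ppbp without replicate 2 (0.0564). Under median centring Cd6 was at -0.13 (adjusted p = 0.706), Np4 at -0.05 (0.901) and Alas2 at -0.29 (0.338). With the slide as a random block Np4 and Tpsab1 missed the threshold (adjusted p = 0.0729 and 0.0613). The Cd3d and Il7r probes carried a hexamer of the kind described for the highest ratios.

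Fibroblast and matrix genes gave the smallest p of the 38 lists: 20 of 22 measured members were lower and none higher, also when adjusted over the list alone (adjusted p = 1.6e-07). Beside Col3a1 and Thbs1, the collagen gene Col1a2 fell to -1.95 ± 0.08, with a second probe at -1.35, and the mesenchymal filament gene Vim to -1.49 ± 0.20. Matrix metalloproteinases and their inhibitors had 8 of 16 lower and 1 higher (adjusted p = 0.00418; 9 and 1 adjusted over the list alone), with Mmp10 at -1.54 ± 0.11, Mmp13 at -1.07 ± 0.23 on 3 arrays, Mmp7 at -1.04 ± 0.15 and Mmp19 at -0.75 ± 0.10. Enteric neuron and glia markers had 6 of 13 lower and 1 higher (adjusted p = 0.0151; 7 and 1 adjusted over the list alone), including Gfap at -0.74 ± 0.17 on 3 arrays, and Vip at -0.60 ± 0.14 and Prph at -0.48 ± 0.14 on 2. The neuron and glia list did not pass under median centring (adjusted p = 0.15), in fry (0.485) or with both channels well above background on all arrays (0.078). Gfap missed the threshold without replicate 1 or 2 (adjusted p = 0.0508 and 0.0691), Mmp13 without replicate 1 (0.055) and Prph without replicate 4 (0.0531). Vip and Prph rest on the arrays of slide 1 and missed it under median centring (-0.11 and -0.01, adjusted p = 0.751 and 0.973) and with the slide as a random block (0.0529 and 0.073). The adjusted p with an estimated correlation was 0.587 for fibroblast and matrix genes, 0.608 for metalloproteinases and 0.705 for neurons and glia.

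Antimicrobial and regenerating family genes had 9 of 13 members lower and 1 higher (adjusted p = 0.00418; 9 and 2 adjusted over the list alone), led by S100a8, Reg1a, Reg3a and S100a9. Complement and acute phase genes had 8 of 15 lower and 3 higher (adjusted p = 0.0142; 11 and 3 adjusted over the list alone), with C4a at -0.97 ± 0.10, Serping1 at -0.62 ± 0.13, A2m at -0.61 ± 0.11 and C1r at -0.56 ± 0.15. Under median centring the complement list did not pass (adjusted p = 0.0642). With both channels well above background on all arrays neither list did (adjusted p = 0.5 for antimicrobial and 0.353 for complement genes). C1r missed the threshold without replicate 1, 2 or 4 (adjusted p = 0.0762, 0.0792 and 0.055). The adjusted p with an estimated correlation was 0.587 for antimicrobial and 0.608 for complement genes.

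Among the genes named by the rule, the highest ratios belonged mostly to genes whose probes had short sequences in common. Over all tested probes, a few without these sequences had mean log2 ratios above 2.5, where no probe with them lay. Rab33a, whose probe is placed at positions 134998256 to 134998315 of chromosome X in rn3, reached 2.29 ± 0.19 (n = 4, adjusted p = 0.00404). Shc2, Ankrd28, Prkag2, Hoxa11, Cldn11, Vcsa2, Olfm2, Ceacam20, Hsd3b2, Tshz3 and B4galt2 followed between 2.20 and 1.98. Of these 12 probes, 11 carried at least 1 of 13 hexamers, such as CACCTC and ACCTCA, that were over-represented among the highest probes, against 16.3% of all tested probes and 1 of the 12 lowest genes. A second probe of Prkag2 gave 0.74 and a second probe of Hoxa11 gave 0.55. Without the probes carrying a hexamer, 113 probes were higher and 289 lower by at least 1 on the log2 scale, in place of 475 and 309. This fall is partly built in, as the hexamers were picked from the highest of these probes. All 17 lists still passed in camera at the preset correlation, with absorptive colonocyte markers at an adjusted p of 0.0485. None of the 17 had passed with an estimated correlation and all probes. The probes of Slc9a2, Cdx1, Muc2, Muc4, Elovl5, Ndufs3, Ndufc2, Rpl6, Myc, Trpm5, Robo4, Pnpla2, Aldh1a1, Ucp2, Acadvl, RT1-DOa and Pla2g2a, all higher, carried a hexamer too. So did those of Cd3d, Il7r, Mmp13, Serping1, A2m, Alox5ap, Slc7a2 and Cd40, all lower.

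**Figure D2:**
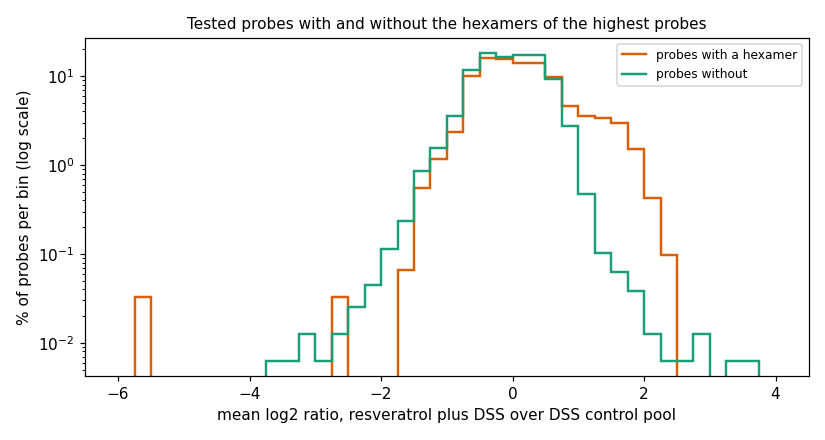
Share of probes (vertical axis, log scale, percent per bin) by mean log2 ratio of resveratrol plus DSS over the DSS control pool (horizontal axis), for tested probes with and without 1 of the 13 hexamers. Probes with a hexamer are more frequent above 1, where 362 of the 475 called probes carried one, against 34 of the 309 called below -1. The hexamers were picked from the highest of these same probes, so the difference is partly built in.

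Tight junction and adhesion genes had 10 of 22 members higher and none lower, also when adjusted over the list alone (adjusted p = 0.00315), with Cldn15 followed by Dsc2 at 0.99 ± 0.10, Cldn7 at 0.98 ± 0.19 and Cldn3 at 0.65 ± 0.10. A hexamer was carried by the probes of 1 of the 22 members, and on slide 2 alone the list did not pass (adjusted p = 0.0645). Absorptive colonocyte markers had 12 of 31 higher and 1 lower (adjusted p = 0.0072; 11 and 1 adjusted over the list alone), with the sodium/proton exchanger gene Slc9a2 at 1.19 ± 0.15, the intestinal transcription factor gene Cdx1 at 1.12 ± 0.11, Krt20 at 1.09 ± 0.30 on 2 arrays and the monocarboxylate transporter gene Slc16a1 at 1.05 ± 0.10. The probes of 7 of its 31 members carried a hexamer. The colonocyte list did not pass on probes with values on all 4 arrays (adjusted p = 0.062) or in fry (0.0567). Krt20 missed the threshold without replicate 1 (adjusted p = 0.0627). The adjusted p with an estimated correlation was 0.631 for junction genes and 0.705 for colonocyte markers. Goblet cell markers had 8 of 18 higher and 1 lower and did not pass as a list (adjusted p = 0.0746), but passed as higher in 6 of 25 alternatives (smallest adjusted p = 0.00249, under median centring). The mucin gene Muc2 rose to 1.63 ± 0.20. Muc4, whose brightest probe was saturated in Cy5 on all arrays, was at least 2.95-fold higher by that probe (adjusted p = 0.00409), and the log2 ratios of the gene's 5 probes ranged from 0.28 to 2.04.

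Oxidative phosphorylation genes had 18 of 45 members higher and none lower, also when adjusted over the list alone (adjusted p = 0.000546), with Ndufs3 at 1.36 ± 0.16 and Atp5f1a at 1.10 ± 0.10 on 3 arrays, Ndufc2 at 0.88 ± 0.14 on 2 and Sdhd at 0.78 ± 0.10. Cholesterol and fatty acid synthesis genes had 11 of 28 higher and 1 lower (adjusted p = 0.0139; 13 and 1 adjusted over the list alone), with Elovl5 at 1.86 ± 0.19, Fasn at 0.83 ± 0.22 and Srebf2 at 0.80 ± 0.10; the second Fasn probe gave -0.30. Ribosomal protein genes had 18 of 74 higher and 1 lower (adjusted p = 0.00644; 10 and 0 adjusted over the list alone), with Rps15, saturated in Cy5 on all arrays, at least 3.17-fold higher, Rpl41 at 1.13 ± 0.13 on 3 arrays, Rpl6 at 0.95 ± 0.15 and Rps3 at 0.84 ± 0.14 on 2. The adjusted p with an estimated correlation was 0.705 for oxidative phosphorylation and for cholesterol and fatty acid genes and 0.825 for ribosomal genes. The probes of 9 of the 45, 4 of the 28 and 6 of the 74 members carried a hexamer. On slide 2 alone neither oxidative phosphorylation nor cholesterol genes passed (adjusted p = 0.118 and 0.429), and the direction of the ribosomal list turned to lower (adjusted p = 0.442). Cholesterol genes missed the threshold without replicate 1 (adjusted p = 0.0748) and without replicate 2 (0.082), as did ribosomal genes (0.0667 and 0.503) and Fasn (0.0828 and 0.0759). On probes with values on all 4 arrays the cholesterol and ribosomal lists did not pass (adjusted p = 0.105 and 0.0876). In fry none of the 3 did (0.0766 for oxidative phosphorylation, 0.0539 for cholesterol and 0.26 for ribosomal genes).

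**Figure D3:**
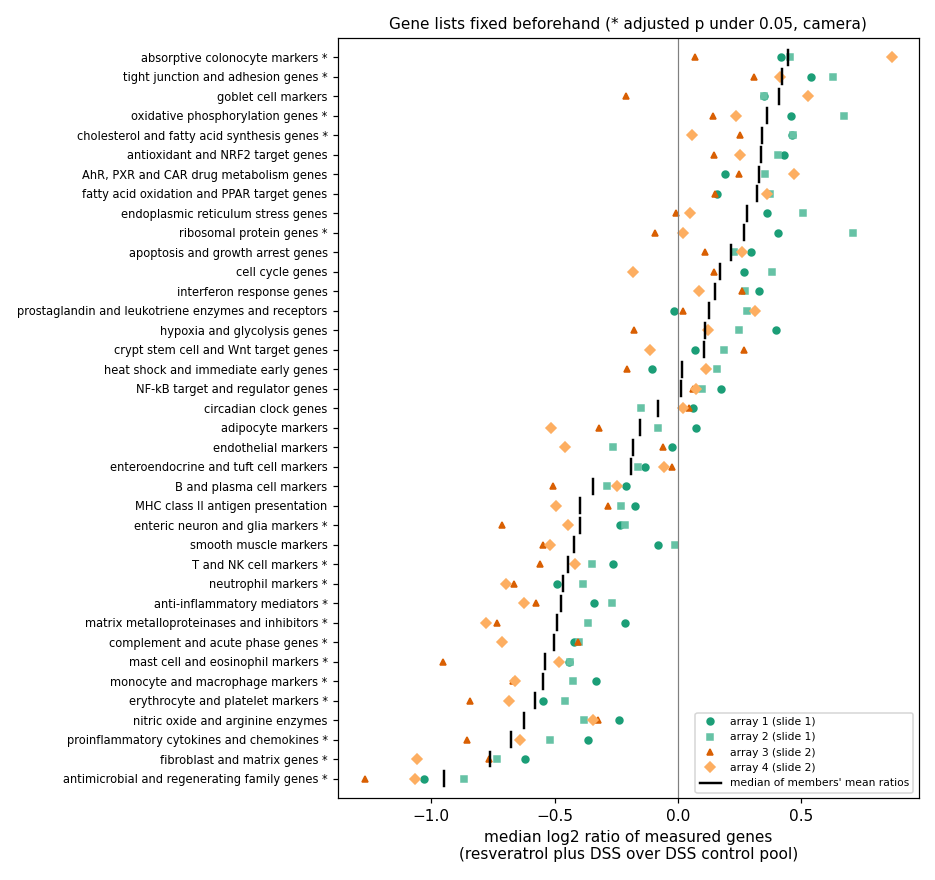
Median log2 ratio of resveratrol plus DSS over the DSS control pool (horizontal axis) of the measured members of each of the 38 gene lists (vertical axis) on each array; black bars give the median of the members' mean ratios and asterisks mark an adjusted p under 0.05 in camera. Antimicrobial and regenerating family genes have the lowest median, -0.95, and absorptive colonocyte markers the highest, 0.44.

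The remaining lists did not pass with all arrays and the main settings, and some passed in alternatives, among them planned ones such as median centring. Smooth muscle markers had 3 of 16 members lower and none higher (adjusted p = 0.0758; 0 adjusted over the list alone), with Des at -1.40 ± 0.46 and Cald1 at least 1.35-fold lower. As a list they passed as lower in 6 of 25 alternatives, among them without replicate 1 (adjusted p = 0.0165), without replicate 2 (0.0158) and on slide 2 alone (0.000416). Des missed the threshold without any 1 of the arrays (adjusted p = 0.056, 0.0588, 0.0701 and 0.0516) and was at -0.81 without replicate 4. Cald1 missed it without replicate 1 or 2 (adjusted p = 0.0675 and 0.0725). Endothelial markers had 3 of 11 higher and 5 lower (adjusted p = 0.32), with Robo4 at 1.32 ± 0.18 and Egfl7 at -1.23 ± 0.38; without the hexamer probes they were lower as a list (adjusted p = 0.0253), as on probes with 4 values (0.0189) and on slide 2 alone (0.0294). Without replicate 3 Egfl7 was at -0.71, and it missed the threshold without replicate 1, 2 or 4 (adjusted p = 0.0584, 0.0686 and 0.0721). Adipocyte markers had 2 of 10 each way (adjusted p = 0.501), with Pnpla2 at 1.68 ± 0.22 and Cidea at -0.70 ± 0.10. B and plasma cell markers had 4 of 8 lower and 1 higher (adjusted p = 0.15, and 0.0422 in 1 alternative, with no filter on dim probes), with Mzb1 at -0.66 ± 0.17 on 3 arrays and Cd38 at 0.52 ± 0.15. Mzb1 was at -0.44 without replicate 3 and missed the threshold without replicate 1 or 2 (adjusted p = 0.0609 and 0.0745), as Cd38 did without replicate 1, 2 or 4 (0.119, 0.109 and 0.0943). Enteroendocrine and tuft cell markers had 3 of 15 higher and 4 lower (adjusted p = 0.333), with Trpm5 at 1.77 ± 0.23 on 3 arrays and Scg3 at -0.73 ± 0.13 on 2. Crypt stem cell and Wnt target genes had 2 of 16 each way (adjusted p = 0.856), with Myc at 1.87 ± 0.18 and Tcf7 at -0.53 ± 0.09, and cell cycle genes had 7 of 37 higher (adjusted p = 0.235; 0 adjusted over the list alone), with Kif20a at 0.81 ± 0.22 on 2 arrays and Ube2c at 0.76 ± 0.22. The cell cycle list passed as higher without replicate 4 (adjusted p = 0.0216) and on slide 1 alone (0.0164). Kif20a missed the threshold without replicate 4 (adjusted p = 0.0572) and Ube2c without replicate 1 or 2 (0.108 and 0.112).

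Antioxidant and NRF2 target genes had 16 of 37 members higher and 4 lower but missed the threshold (adjusted p = 0.0517), with Txn1 at 1.31 ± 0.31 on 3 arrays and Abcc3 at 1.02 ± 0.12; without the hexamer probes the list passed (adjusted p = 0.0306), as in 11 of 25 alternatives in all (smallest adjusted p = 0.00238). Txn1 missed the threshold without replicate 1 or 2 (adjusted p = 0.0888 and 0.0815). Drug metabolism genes of the AhR, PXR and CAR receptors had 12 of 25 higher and 4 lower (adjusted p = 0.0947), with Aldh1a1 at 1.96 ± 0.17 and Sult2b1 at least 1.61-fold higher. Fatty acid oxidation and PPAR target genes had 14 of 35 higher and 2 lower (adjusted p = 0.0773), with Ucp2 at 1.05 ± 0.12 and Acadvl at 0.93 ± 0.11; it passed in 5 alternatives (smallest adjusted p = 0.0205). Among 30 measured apoptosis and growth arrest genes 11 were higher and 4 lower (adjusted p = 0.12), with Perp at 0.69 ± 0.16 on 3 arrays, past the threshold neither without replicate 1 nor without replicate 4 (adjusted p = 0.0967 and 0.0812). Endoplasmic reticulum stress genes had 7 of 25 higher and 2 lower (adjusted p = 0.103), with Creld2 at 0.86 ± 0.16 and Dnajb11 at 0.84 ± 0.11, and passed in 6 alternatives (smallest adjusted p = 0.0152). The drug metabolism and apoptosis lists passed in fry alone (adjusted p = 0.0326 each).

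Interferon response genes had 8 of 20 members higher and 1 lower (adjusted p = 0.32), with Irf9 at least 1.28-fold higher and Oasl at 0.66 ± 0.10. MHC class II genes had 2 of 8 each way (adjusted p = 0.357), with RT1-DOa at 1.15 ± 0.21 and Ctss at 0.71 ± 0.10. Prostaglandin and leukotriene genes had 3 of 10 each way (adjusted p = 0.927), with Pla2g2a at 1.22 ± 0.24 and Alox5ap at -0.93 ± 0.18 on 2 arrays. Nitric oxide and arginine enzymes had 2 of 9 higher and 4 lower (adjusted p = 0.338), with Slc7a2, on 3 arrays, and Arg1 at -0.85 each. NF-kB target and regulator genes had 5 of 22 higher and 3 lower (adjusted p = 0.82), with Vcam1 at -1.05 ± 0.12 and Cd40 at -0.94 ± 0.25 on 3 arrays, whose second probe was higher at 0.41. Cd40 was at -0.57 without replicate 3 and missed the threshold without replicate 1 or 2 (adjusted p = 0.0673 and 0.0544). Hypoxia and glycolysis genes had 5 of 28 each way (adjusted p = 0.794), with Pfkl at 0.77 ± 0.10 and Hk2 at 0.62 ± 0.10. Heat shock and immediate early genes had 5 of 27 higher and 7 lower (adjusted p = 0.723), with Dusp1 and Hspb1 both at -0.88, and circadian clock genes 4 of 13 higher and 2 lower (adjusted p = 0.927), with Nr1d1 at 0.88 ± 0.22 and Nr1d2 at least 1.16-fold higher. Both missed the threshold without replicate 1 (adjusted p = 0.0779 and 0.0792) or 2 (0.0795 and 0.08). The median and the mean of the heat shock, circadian and NF-kB lists differed in sign. When adjusted over the list alone, the higher and lower members numbered 2 and 5 for B and plasma cells, 2 and 1 for crypt stem cells, 13 and 5 for drug metabolism, and 6 and 1 for endoplasmic reticulum stress. They numbered 2 and 4 for MHC class II, 3 and 4 for prostaglandins, and 2 and 5 for nitric oxide enzymes. Apart from the smooth muscle and cell cycle lists, the other lists that did not pass had the same counts adjusted over the list alone.

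Log2 ratios of the 4 arrays correlated across probes with a mean Pearson r of 0.75 over the 6 pairs, 0.89 between the arrays of slide 1 and 0.72 between those of slide 2; probes are not independent replicates, and all arrays are labelled against the control pool and have the same dye orientation. Because Cy5 always held the resveratrol sample, a dye effect of a probe cannot be separated from the treatment, and because the ratio was tested against 0, the control's own spread is left out. The bright spots of slide 2 often carried an outlier flag (53.5% and 56.3% of the brightest decile, against 17.2% and 15.9% on slide 1), so many bright genes rest on 2 or 3 arrays. Ptges, Np4, Lyz2, Cd6, Scg3, Kif20a, Vip, Prph, Alas2, Ndufc2 and Rps3 rest on slide 1 alone. The ratios of Ccl3, Arg1, Vcam1, Il7r, Il4 and C1r rest on a Cy5 signal well above background on 1 or 2 arrays. Those of Nr1d1, Cd38, RT1-DOa, Oasl, Hsd3b2 and Il7r rest on such a Cy3 signal, so these sizes are uncertain.

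Second probes not given above were at -1.51 for Serping1, -0.78 for Mcpt1, -0.74 for Il1rn, -0.62 for Mmp19, -0.58 for Scg3 and -0.54 for Cd6. They were at 0.83 for Dsc2, 0.82 for Abcc3, 0.65 for Acadvl, 0.51 for Srebf2 and 0.49 for Ctss and Ndufc2.

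Several named genes missed the threshold in other settings. The wider standard error, which allows the control pool a spread, removed the most: Ptges, Nos2, Il1b, Il4, Socs3, Pla2g2a, Alox5ap, Cd40, Np4, Cd163, Cd3d, Gzmb, Cd6, Il7r, Mzb1, Cd38, Hdc, Tpsab1, Mcpt1, Mcpt4, RT1-DOa, Serping1, A2m, C1r, Krt20, Scg3, Tcf7 and Kif20a. It also removed Ube2c, Cldn7, Des, Cald1, Mmp13, Gfap, Vip, Prph, Egfl7, Ppbp, Alas2, Txn1, Sult2b1, Fasn, Creld2, Nr1d1, Nr1d2, Perp, Ndufc2 and Rps3. Under median centring these were Np4, Prph, Ptges, Socs3, Cd6, Mcpt1, Mcpt4, Scg3, Vip, Alas2, Alox5ap, Fcgr3a, A2m, Tcf7 and Gfap. With processed signals they were Np4, Krt20, Prph, Ptges, Socs3, Cd3d, Gzmb, Cd6, Mzb1, Mcpt1, Scg3, Vip, Alas2, Fasn and Perp. With the slide as a random block Kif20a, Np4, Prph, Vip, Tpsab1, Des, Egfl7 and Cd38 missed it. An intensity trend in the prior removed Kif20a, Np4, Krt20, Prph, Ptges, Cd6, Vip and Rps3. Requiring both channels well above background on all arrays removed Kif20a, Np4, Krt20, Prph, Vip, Tpsab1, Ube2c, Des and Egfl7. In the authors' table Kif20a, Krt20, Txn1 and Nr1d2 missed it, and with array weights Des did. Removing base composition lost Np4, Prph, Egfl7 and Cd38, using no background correction lost Np4, Krt20 and Prph, and an offset of 0 lost Kif20a. On slide 2 alone Fasn, Perp, Fcgr3a, Tcf7, Tpsab1, Ube2c, Egfl7, Nr1d1, Nr1d2, Nos2, Pla2g2a, Cd38, Hdc, RT1-DOa, C1r and Cldn7 missed it. So did Cldn3, Cald1, Sult2b1, Creld2, Irf9, Srebf2, Dnajb11, Pfkl, Hk2 and Rpl6.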

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

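No test here was chosen after its result was seen, as one rule for a value far from the others was applied to all results with 4 arrays, and chance marks about 1 in 20. Of 133 results with values on all 4 arrays, 9 had an array far from the others. Array 3 stood apart for Hdc at -3.01, Egfl7 at -2.79, Fcgr3a at -0.74 and the median of mast cell and eosinophil markers at -0.95. Array 4 stood apart for Col3a1 at -3.325, Srebf2 at 0.52 and the median of complement and acute phase genes at -0.71. Ccl3 on array 1, at -0.74, and Sdhd on array 2, at 1.02, were the other two.

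Spike-in control spots, which the comparison does not use and whose nominal ratios are not known here, gave mean log2 ratios from -1.002 to 0.678 over the 6 spike-in probes well above background on all arrays.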

How the results depend on the processing

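Under 22 alternatives, the named genes kept their direction wherever they were tested, and no probe called in both settings changed direction. The added settings (hexamer probes left out, base composition removed, 4 values, single slides, and for lists also the prior, the slide block and the kept outlier spots) were chosen after seeing the data. No paired analysis was possible because the arrays hold a single group against the control pool. Except where stated, the cause was not tested. Of 125 named genes 49 lost their call under the wider standard error, by its construction, and 1 to 22 without 1 replicate. Signal over background limits what dim genes such as Tnf and Il6 can show.

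Probes called numbered 8886, with 4597 higher, 4289 lower and 784 by at least 1 on the log2 scale. Requiring both channels well above background on all arrays gave 4551, 2584 and 1967, with fewer probes tested. The wider standard error gave 2180, 1456 and 724, by its construction. On slide 2 alone, with 2 arrays, they were 1749, 747 and 1002. Processed signals gave 2795 lower and 2127 large changes, median centring 1839 and 1657, and probes with 4 values 2831 lower. Large changes numbered 1228 with offset 0, 2140 in the authors' table, 1516 with outlier spots kept and 402 without hexamer probes, the last partly by construction. Leaving out an array gave 3410 to 8964 called, 1946 to 4751 higher, 1426 to 4213 lower and 591 to 757 large; the lowest totals came without replicate 1 (3463) and without replicate 2 (3410).

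Of the lists, 5 were higher and 12 lower. With an estimated correlation 0 and 0 passed, on genes with 4 values. Higher lists numbered 9 with median centring, 9 with no dim filter, 9 with outlier spots kept, 9 on slide 1 alone, 8 with array weights, 2 with 4 values and 1 on slide 2 alone. Without 1 replicate they numbered 3 to 8, with 3 without replicate 1 or 2. The strict filter left 6 lists lower, and lost cytokine, macrophage, T and NK cell, complement, antimicrobial and neuron genes. Ribosomal genes turned to lower on slide 2 alone (adjusted p = 0.442, against 3.06e-11 to 0.825 over all alternatives) and circadian genes to higher in fry (adjusted p = 0.0336). The mean correlation of arrays was 0.67 (0.6652) with no dim filter, against 0.75.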

Other observations

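All tests here were chosen after the result was seen, except the test on acinar genes not looked at before. Probe sequence and ratio were related on the high side. In 100 random halvings of the genes, hexamers found in one part were carried by a median of 80.9% of the highest probes of the other part, against 14.1% of its other probes, and no hexamer passed the same threshold among the lowest probes, which were fewer (77 against 176) and so gave less power. A candidate explanation is a shared labelled sequence that binds such probes whatever their gene: within a gene, probes with 3 or more hexamers lay above the gene's other probes by a median of 0.76 on the log2 scale over the halvings (range 0.46 to 1.24), and 97 of the 100 gave a p under 0.05 by random sign flips. The halvings redraw the same genes and are not independent. Each such test rested on a median of 22 genes (range 4 to 38). Where all probes of a gene read the same transcripts, their levels alone predict no such difference, and the median sign-flip p was 0.00075. Whether the probes of a gene read the same transcripts was not tested. A dye effect that depends on probe sequence would also give such a difference. As no dye was exchanged, it cannot be told apart from a shared labelled sequence. By array, probes with a hexamer lay above those without by medians of 0.29, 0.15, 0.12 and 0.32 on arrays 1 to 4. Probes with a hexamer were also brighter, by a median of 0.55 in log2 intensity over the halvings (range 0.42 to 0.71). Brightness was not adjusted for in these hexamer tests. Base composition is argued against as the whole cause, since the difference of hexamer probes was 0.22 before and 0.20 (0.2046) after it was removed.

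The called probes make up 47.1% of those tested. With 4 arrays only 8 sign patterns exist, too few for a share under 0.05: the real pattern called 8886 probes (1 of the 8 patterns gave as many) and the highest of the others 0. By an unadjusted p under 0.05 in limma the real pattern gave 11150 and the others between 24 and 1529. All arrays have the same dye orientation and a control pool in Cy3, so effects of dye or pool would also give the real pattern the most probes. These counts therefore cannot tell such effects from the treatment, and no conclusion is drawn from them.

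Pancreatic enzyme genes were lower beyond Amy2a3 and Ctrb1: of 28 acinar genes listed, 13 were lower. Of all 28, whether lower or not, 11 were well above background in Cy5 on at least 3 arrays, and 1 belongs to another list. Pancreatic RNA in the control pool is a candidate source. Of 19 genes not looked at before, 11 were well above background in Cy3 on at least 3 arrays and 7 of these were lower; beforehand, most of the 19 had been asked to be both, so they met neither this nor the bound that would have excluded the source. The median of the 10 tested, -0.44, lay at the 1.5 percentile of 10000 random lists of like brightness. Against it, Pnlip, Clps and Cpa1, abundant in acinar cells, were not well above background on 3 arrays, and Pla2g1b was higher, so the source stays open.

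At the preset correlation, some stromal and leukocyte lists were lower (fibroblast, neuron and glia, neutrophil, macrophage, T and NK, and mast cell) and junction and colonocyte lists higher, none of them with an estimated correlation (adjusted p from 0.587 to 0.705); smooth muscle markers passed as lower in 6 of 25 alternatives and endothelial markers in 3. An equal loss of every kind of non-epithelial tissue would lower fibroblast, smooth muscle, neuron and glia, endothelial and adipocyte genes alike, if their markers are equally specific. Their medians without hexamer probes were -0.77, -0.40, -0.40, -0.45 and -0.27 in that order. The lists differed by permutation over genes, which are not independent (p = 0.0027, 0.0013 with brightness removed and 0.00064 with hexamer probes). On that condition this argues against an equal loss as the whole cause, but not against an unequal loss. The difference rested on the fibroblast list, as without it the other 4 gave a permutation p of 0.88. All 5 medians were negative, so a loss of such tissue stays open, and how specific the markers are was not tested. With hexamer probes included, smooth muscle medians were -0.08 and -0.01 on slide 1 but -0.55 and -0.52 on slide 2. Those of adipocyte markers were 0.07 and -0.08 on slide 1 and -0.32 and -0.51 on slide 2. The junction and colonocyte lists stayed higher in camera without the hexamer probes, colonocyte markers narrowly (adjusted p = 0.0485 against 0.0072 with them). For the junction list this could hardly have come out otherwise, as only 1 of its 22 members carried a hexamer and was not higher. Colonocyte markers had a median of 0.89 with a hexamer and 0.30 without. The hexamer probes are therefore not the whole of the colonocyte result but may account for part of it. A difference in the extent of inflammation or of matrix deposition remains open and was not tested.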
